A study of Homo sapiens with 4 samples.

How the data were processed

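RNA sequencing values of 4 libraries were analysed, 1 each from A375 and SK-MEL-28 melanoma cells treated with siNC or with an siRNA against LINC01291. Per the labels' protocols, total RNA was enriched with oligo(dT) beads and sequenced on an Illumina instrument, and reads were trimmed and freed of duplicates with fastp, checked with FastQC, freed of ribosomal RNA, aligned with HISAT2, assembled with StringTie and counted with HTSeq. The submitters' processing notes name the genome build hg19 and the tools DESeq2 and edgeR without a role or version. The table holds 17903 Ensembl IDs, of which 202 are not in the basic set of GENCODE release 29. Which annotation release was counted is not given in the sources used here, and coordinates are given only from GENCODE 29 on GRCh38. Strand-specific counting is not stated in the sources used here, so antisense genes are treated as uncertain.

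The counts are whole reads per gene as the authors deposited them, counted with HTSeq per the labels' protocols and not normalised. The deposited CPM are counts over each library's whole count total, scaled by the authors before genes of low expression were left out of the table. The deposited FPKM equal the CPM divided by a single length per gene, as the authors computed them. The deposited TPM were scaled by the authors to the same sum in each library, per the file headers, and were not used for any comparison. The table lists 18175 genes and loci, of which 272 are loci assembled by the authors and 2812 are named only by an identifier; the smallest FPKM sum over the 4 libraries is 1.00, and counts of genes outside the table made up 0.303, 0.343, 0.215 and 0.238% of the libraries (A375 siNC, A375 siLINC01291, SK-MEL-28 siNC, SK-MEL-28 siLINC01291). All columns were mapped to a library through the library names in the labels.

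Depth was 30879719, 31815336, 29416145 and 29351240 counts, with 12643, 12838, 11791 and 11993 genes at an FPKM of at least 1. MT-CO1 took the largest share of counts in 3 libraries (0.730, 1.48 and 1.45%) and EEF1A1 in A375 siLINC01291 (0.737%). The floor was set at 3 counts, which is a CPM of about 0.0972 in A375 siNC and 0.102 in SK-MEL-28 siNC. Counting precision of single genes is given as exact binomial 95% intervals of the ratio of a pair of libraries.

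Log2 ratios of siLINC01291 to siNC were computed within each line from counts with TMM factors and a prior count of 2 in edgeR 4.0.16 (R 4.3.3). A gene was taken as expressed in a line at an FPKM of at least 1 in either of its 2 libraries. Over both lines, edgeR's quasi-likelihood test with the cell line as a block and Benjamini-Hochberg adjustment was run on 13501 genes with an FPKM of at least 1 in at least 2 libraries, which leaves 1 residual degree of freedom; the same model tested SK-MEL-28 against A375. The pairing comes from the cell line, since both libraries of a pair stem from the same line. Within a line, 28 gene lists (643 genes, fixed by hand from general knowledge) were compared with 10000 random lists of the same size matched in 20 bins of mean expression, for lists with at least 5 expressed members. Over both lines, they were tested with camera of limma 3.58.1, with the preset correlation of 0.01 and, as an alternative, with an estimated one. Agreement of the lines was measured across genes expressed in both.

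Genes were named by a rule: LINC01291; per line the 12 highest and 12 lowest log2 ratios among genes with an FPKM of at least 5 and a proper symbol; for both lines the 12 highest and 12 lowest by the smaller of the 2 shifts among genes that moved the same way; up to 4 expressed members per described list with the largest mean shift; and IGF1R, MITF, AXL, SOX10, CDKN1A, MKI67, MYC and CCND1. Genes named outside this rule are marked as chosen after their values were seen, and those that can share reads with near-identical copies as uncertain. A few genes that meet the rule are not reported here.

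Words of 7 bases were searched in annotated 3' UTRs of at least 50 bases (GENCODE 29). A single principal protein-coding transcript was searched per gene, so coding sequences and other 3' ends were not covered. The mean log2 ratio of the lines was regressed on the presence of each word with UTR length and GC content as covariates, and the log2 ratios were shuffled over genes 100 times. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for this step and the drawings.

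The calls over both lines, the 2-fold counts within a line, the comparison with random lists and the word search were tested on simulated data. Counts drawn for the 13501 genes with 200 changed genes gave recovery of 66, 94, 100 and 100% at 1.5, 2, 4 and 8-fold in edgeR, with 28 false among 208 calls. Changes were planted only in genes of higher count and were equal in both lines. The spread of the simulated counts was the one estimated by the fit over both lines. Of 100 simulated unchanged lists of 25 genes, 6 stood apart. In a search over 9332 genes with shuffled ratios, a word whose genes were shifted by -0.2 was recovered first. Alternatives were DESeq2 1.42.0, limma on log2(FPKM + 1) with and without quantile normalisation and with a smaller added value of 0.1, DESeq2 size factors, median centring, a prior count of 0.5, an FPKM minimum of 5 or none, thresholds of 1.5 and 3-fold, list means, no cell line term, and, chosen after the data were seen, leaving out genes with CTATGAA or TCTATGA in their 3' UTR. Leaving out a library within a line was not possible with 1 library per group.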

Results

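Gene expression was measured by RNA sequencing in A375 and SK-MEL-28, human melanoma cell lines. In each line, cells treated with an siRNA against the long non-coding RNA LINC01291 (siLINC01291) were set against cells treated with siNC, by its name the negative control siRNA. The treatment label also names EL without explaining it, and whether EL was given to these libraries is not given in the sources used here. The 4 libraries fell into 4 groups of 1 library, so no difference within a line has a replicate check, and values within a line are given as higher or lower, without a p-value. The only replication of the treatment is across the 2 lines. The libraries held 30879719 counts (A375 siNC), 31815336 (A375 siLINC01291), 29416145 (SK-MEL-28 siNC) and 29351240 (SK-MEL-28 siLINC01291) over the 18175 listed genes and loci. Log2 CPM of the pair of libraries correlated across genes with Pearson r = 0.993 in A375 and 0.989 in SK-MEL-28, and with r between 0.814 and 0.826 for libraries of different lines; genes are not independent replicates. Intervals given for single genes within a line are 95% exact binomial intervals and cover counting error only.

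The first comparison asked how far the targeted transcript was lowered. LINC01291 (ENSG00000204792) was lower in the siLINC01291 library of both lines. In A375 it went from 827 to 304 counts (normalised CPM 25.5 to 8.78), which left 34.5% of the siNC level (interval 30.2 to 39.4%). In SK-MEL-28 it went from 998 to 454 counts (normalised CPM 36.7 to 16.3), which left 44.5% (interval 39.7 to 49.7%). Over both lines LINC01291 fell by 1.34 on the log2 scale (SE 0.13, adjusted p = 0.0171 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in 2 of 2 lines). In the GENCODE 29 annotation of GRCh38, LINC01291 is a lincRNA on the + strand of chromosome 2 from 74918148 to 74938418. It lies between genes that were chosen for naming after their values were seen, HK2 (74833981 to 74893359), which codes for the glycolytic enzyme hexokinase 2, and POLE4 (74958492 to 74970128), which codes for a small DNA polymerase epsilon subunit. A second lincRNA, LINC01293 (ENSG00000230836, 74940258 to 74942670), begins 1839 bases downstream on the same strand. LINC01293 was lower by more than LINC01291 itself, from a normalised CPM of 38.7 to 10.8 in A375 (log2 ratio -1.83) and of 51.2 to 17.2 in SK-MEL-28 (-1.57), and fell by 1.70 over both lines (SE 0.12, adjusted p = 0.0122, same edgeR test). HK2 had log2 ratios of -0.32 in A375 and -0.19 in SK-MEL-28 and POLE4 of 0.12 and 0.17, and neither passed the test over both lines (edgeR adjusted p = 0.203 and 0.460).

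**Figure D1:**
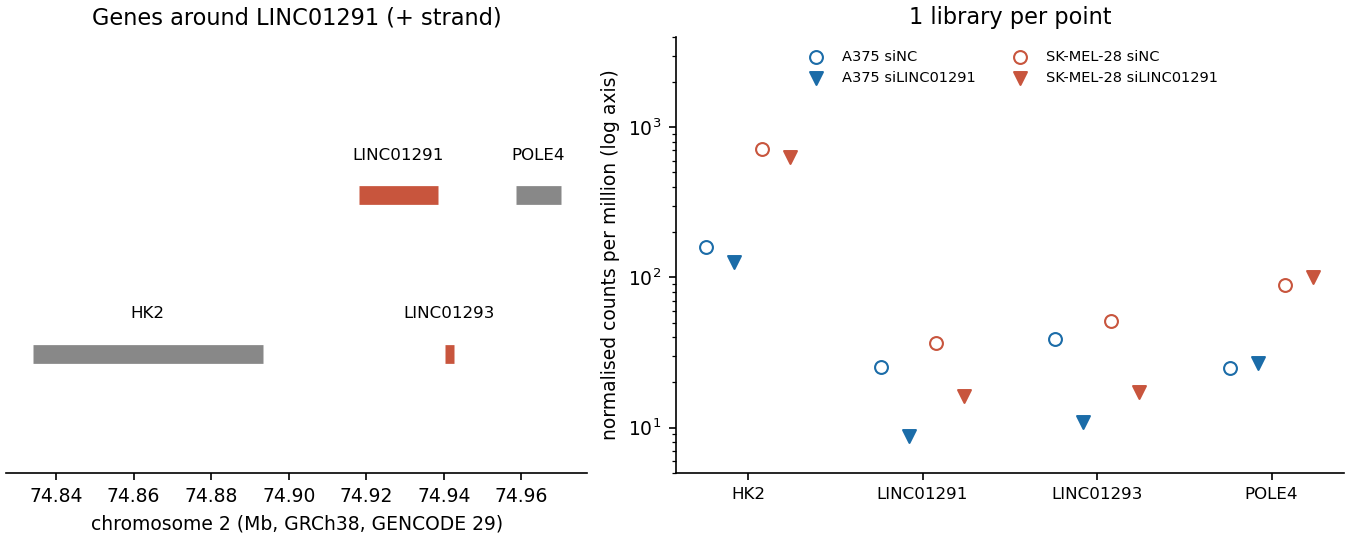
Left, position of HK2, LINC01291, LINC01293 and POLE4 on chromosome 2 (GRCh38, GENCODE 29). Right, TMM-normalised CPM of each gene on a log axis, 1 point per library (open circles siNC, triangles siLINC01291); LINC01291 and LINC01293 were lower with siLINC01291 in both lines, to 8.78 and 10.8 in A375 and to 16.3 and 17.2 in SK-MEL-28.

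The comparison over both lines asked which genes shifted with siLINC01291 in A375 and SK-MEL-28 together. Genes that fell outnumbered those that rose (91 against 30). The test was rerun without the genes that hold CTATGAA or TCTATGA in their 3' UTR, a choice made after the data were seen. Then 65 fell and 109 rose. Of the 91 fallen genes, 72 hold either word and were left out, and 19 were called again. Most of the 65 and of the 109 were thus new calls of the refit. SLC7A11, the cystine importer that feeds glutathione synthesis, fell most of the genes that were lower in both lines (log2 ratio -2.27 in A375 and -1.75 in SK-MEL-28, SE of the joint estimate 0.14, adjusted p = 0.0122 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was 4.82-fold lower in A375 and 3.36-fold lower in SK-MEL-28. The transcriptional coactivator WWTR1 (-1.61, SE 0.18, edgeR adjusted p = 0.0265) and ANKRD1, which codes for an ankyrin repeat protein (-1.89, SE 0.14, edgeR adjusted p = 0.0129), also fell. TPM4, a tropomyosin of the actin cytoskeleton, rose most among protein-coding genes with an FPKM of at least 5 in each line (1.47, SE 0.13, edgeR adjusted p = 0.0133), 2.30-fold higher in A375 and 3.32-fold in SK-MEL-28.

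Of 13501 genes tested with the cell line as a block, 91 fell and 30 rose, and 120 of these 121 had the same sign in both lines. The exception, XAGE1B, had 1 and 2 counts in the SK-MEL-28 libraries. Like signs are largely built in, since the fit's error measures how far the lines disagree. Among the 121, 47 fell and 14 rose at least 2-fold. The median log2 change was -1.01 for the fallen and 0.98 for the risen genes. Other genes named by rule that fell were the disulfide isomerase PDIA6 (-1.45), the succinate dehydrogenase subunit SDHD (-1.58), the vacuolar proton pump subunit ATP6V1G1 (-1.35), the replication factor GINS1 (-1.38), the protein kinase A catalytic subunit PRKACB (-1.42), the CCAAT-binding factor subunit NFYC (-1.45), the decapping factor DCP1A (-1.27) and SMIM13 (-1.53), with adjusted p between 0.0122 and 0.0137 (edgeR). Risen genes named by rule were the glucosidase subunit GANAB (1.13), the endosomal syntaxin STX12 (1.09), the mitochondrial protein FAM210B (1.00), the palmitoyltransferase ZDHHC16 (0.99), the stress granule protein G3BP2 (0.96) and the receptor GPR153 (0.83), with adjusted p between 0.0133 and 0.0383 (edgeR). SPCS2P4 (1.71, SE 0.22) is a pseudogene that can share reads with its parent gene and is uncertain. CHST14 (1.21), BICD2 (1.19) and LBX2-AS1 (0.75) were higher in both lines but did not pass (adjusted p = 0.0914, 0.0726 and 0.0687, edgeR); LBX2-AS1 is antisense and uncertain. Of the genes fixed for naming whatever their values, IGF1R (-0.29, SE 0.09), MITF (0.11, SE 0.11), AXL (-0.19, SE 0.10), SOX10 (0.35, SE 0.10), CDKN1A (-0.25, SE 0.14), MKI67 (-0.26, SE 0.14), MYC (-0.07, SE 0.13) and CCND1 (-0.17, SE 0.07) did not pass (edgeR adjusted p between 0.166 and 0.849).

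This fit has 1 residual degree of freedom, and its calls depend on the model: without the cell line term 0 genes passed in either direction (51 at an unadjusted p under 0.05 in edgeR), limma on log2(FPKM + 1) called 1 risen and 5 fallen genes, and DESeq2 called 99 and 203, which included 28 of the 30 and 86 of the 91. In simulated libraries of this design, 66% of genes changed 1.5-fold and 94% of those changed 2-fold were recovered by edgeR. Limma (there on CPM) recovered 70 and 92%, and DESeq2 36 and 82%. Of the 208 edgeR calls 28 were false, more than the adjusted p threshold of 0.05 aims for. Changes were planted in genes of higher count and alike in both lines, with the spread of this fit, so real recovery may be lower. On the real libraries limma on FPKM called the fewest genes of these 3 tools and DESeq2 the most.

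**Figure D2:**
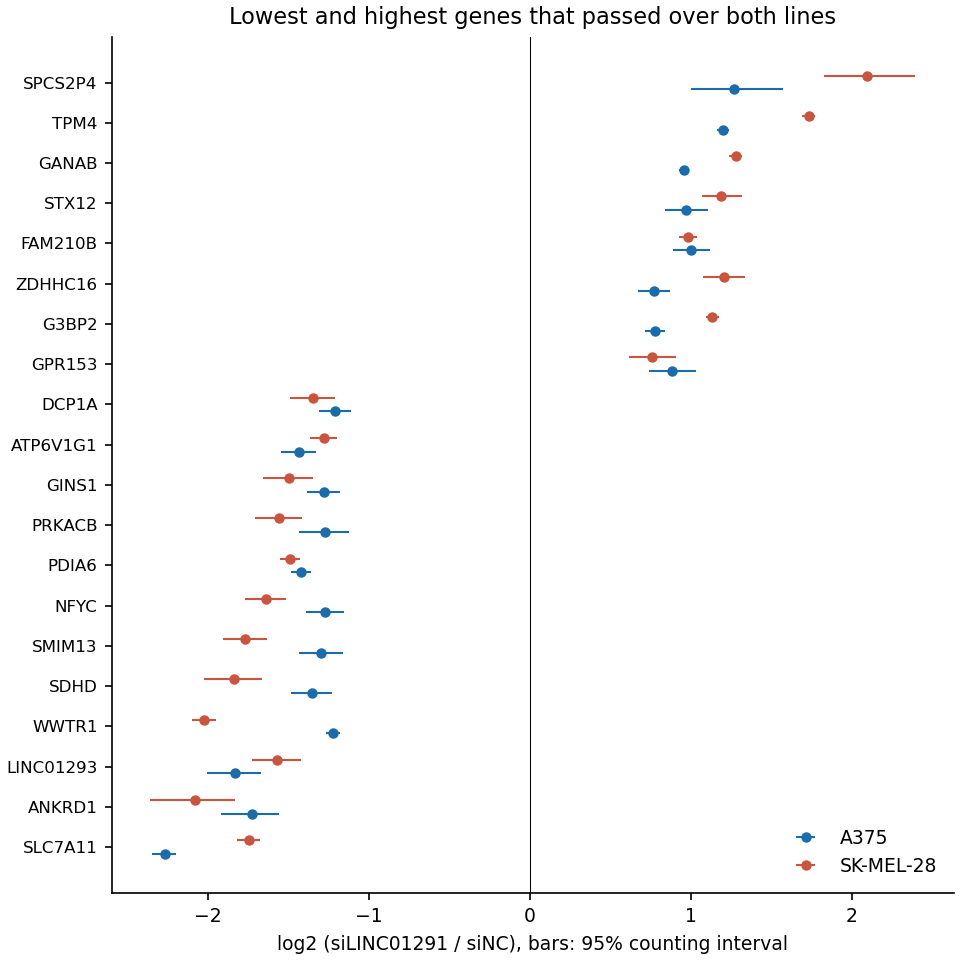
Log2 ratio of siLINC01291 to siNC per line for those of the 12 lowest and 12 highest genes over both lines, ranked by the smaller of the 2 shifts, that passed the test over both lines. Points are 1 pair of libraries each and bars are 95% counting intervals; SLC7A11 lies at -2.27 in A375 and -1.75 in SK-MEL-28, and TPM4 at 1.20 and 1.73.

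The fallen genes shared short sequences in their 3' UTRs. This search was not among the comparisons fixed before the data were examined. Among 16081 words of 7 bases tested in 9332 genes expressed in both lines, with UTR length and GC content as covariates, CTATGAA and TCTATGA went with the lowest log2 ratios (t = -24.9 and -23.6) and held ranks 1 and 2 in each line; the lowest t in 100 shuffles of the ratios over genes was -4.90. Either word was present in the 3' UTRs of 72 of the 86 fallen genes with a searched UTR (83.7%) and of 13.9% of the other 10638 searched genes; the words were picked on ratios that include the fallen genes. SLC7A11, WWTR1, PDIA6, SDHD, ATP6V1G1, GINS1, PRKACB, NFYC, DCP1A and SMIM13 carried at least 1 of the words, whereas the 3' UTRs of ANKRD1, CXCL8, TXNRD1 and JUN did not. Of the genes fixed for naming, IGF1R and AXL carried at least 1 of the words. MITF, SOX10, CDKN1A, MKI67 and CCND1 carried neither, and MYC had no searched 3' UTR. Genes with the joined 8-base word TCTATGAA had a median log2 ratio of -0.18 in A375 (SE 0.03) and -0.31 in SK-MEL-28 (SE 0.03, 335 genes), against 0.00 and 0.01 in the 7182 genes without any of the words. TCTATGAA occurs once in each of the 3 annotated LINC01291 transcripts and in none of LINC01293. At the other end, TCGGAGA went with the highest log2 ratios (t = 9.87, highest of the shuffles 4.75). It was present in 6 of the 28 risen genes searched, CDK14, FAM210B, HABP4, G3BP2, TPM4 and HSDL2 (the last named after its values were seen), and in 1.79% of the other genes; the word was picked on ratios that include these genes.

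**Figure D3:**
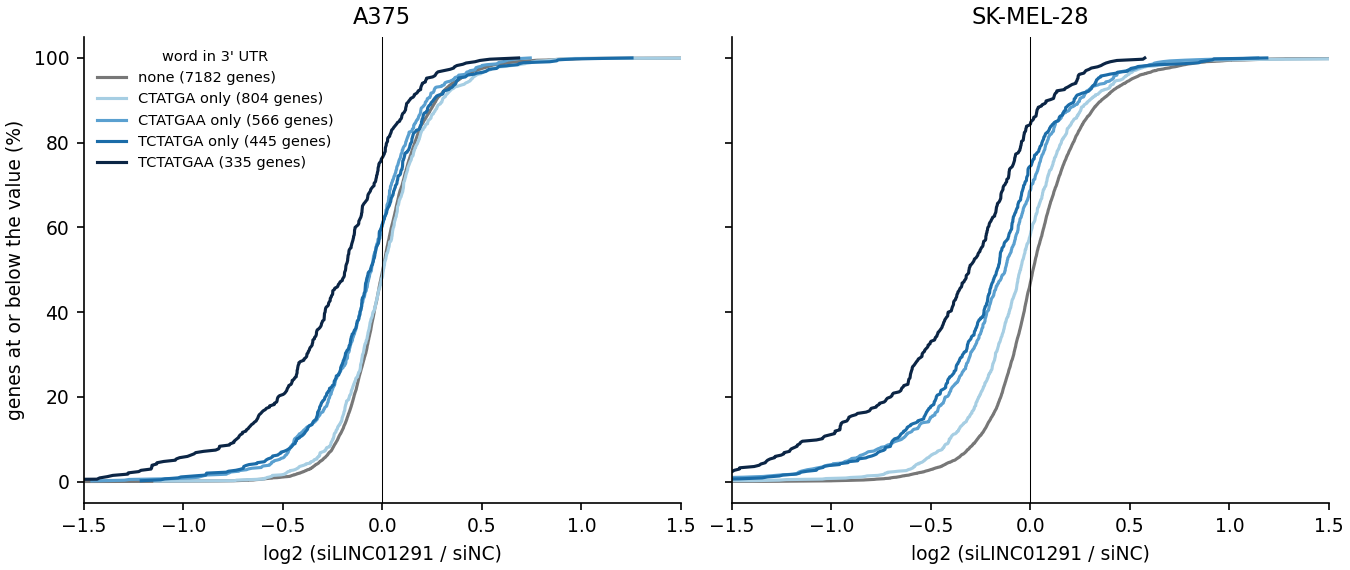
Cumulative share of genes (%) by log2 ratio of siLINC01291 to siNC in A375 (left) and SK-MEL-28 (right), for genes expressed in both lines and grouped by the word their annotated 3' UTR holds. The curve of the 335 genes with TCTATGAA lies to the left of the others, at a median of -0.18 and -0.31; values beyond 1.5 in either direction lie outside the axes.

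In A375, the comparison of siLINC01291 with siNC asked which genes differed in that line alone. CEMIP, which takes part in hyaluronan breakdown, had a log2 ratio of 1.93 (FPKM 7.81 to 30.7), the Wnt and FGF signalling regulator SHISA2 was 3.16-fold higher, and the neuropeptide precursor VGF 2.45-fold higher. XAGE1B, a cancer-testis antigen, was 5.69-fold lower (FPKM 12.3 to 2.19). CHAC1, a glutathione-degrading enzyme induced by ATF4, was 2.90-fold lower, and the metal-binding metallothionein MT2A 2.61-fold lower (FPKM 292 to 116); MT2A has CTATGAA or TCTATGA in its 3' UTR. Of 13244 expressed genes, 123 were at least 2-fold higher and 140 at least 2-fold lower. Also among the largest shifts were GRAMD1B (2.25-fold higher), the cytokine IL11 (2.02-fold higher), FAM114A1 (1.97-fold higher), CDK14 (1.97-fold higher) and COSMOC (2.31-fold higher), an antisense RNA and so uncertain. MT2P1 (2.69-fold lower) is a metallothionein pseudogene whose reads can come from MT2A and is uncertain. XAGE1B belongs to a family of near-identical copies and is uncertain for the same reason. MT2A, SHISA2 and CDK14 also passed the test over both lines (edgeR adjusted p = 0.0182, 0.0265 and 0.0383), although SHISA2 was barely expressed in SK-MEL-28 (FPKM 0.0529 and 0.0707), while CEMIP did not (1.23, SE 0.30, edgeR adjusted p = 0.126). In 13301 genes simulated without any change, 100 differed at least 2-fold between a pair of A375 libraries. The simulation set no expression minimum within the line, so genes expressed only in SK-MEL-28 could count. The 100 therefore cannot be set directly against the 123 and 140. At an FPKM of at least 5, 11 genes were higher and 45 lower of 7419.

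In SK-MEL-28, the same comparison was led in part by other genes. The G protein regulator RGS19 was 4.09-fold higher (FPKM 1.64 to 6.97), the sulfotransferase CHST14 3.51-fold, the opioid growth factor receptor OGFR 3.25-fold and the nucleolar protein NOLC1 3.17-fold higher. WWTR1 was 4.06-fold lower (FPKM 29.3 to 7.39), the secreted Wnt inhibitor DKK1 3.49-fold lower and the surface protein IGSF3 had a log2 ratio of -1.68 (FPKM 79.5 to 25.4). Of 12336 expressed genes, 212 were at least 2-fold higher and 190 at least 2-fold lower. BICD2 (3.18-fold), HABP4 (3.17-fold), the cancer-testis antigen SSX2 (3.03-fold) and the sulfiredoxin SRXN1 (2.87-fold) were also higher, and ANKRD46 (4.43-fold), FAM234B (3.96-fold) and CARNMT1 (3.14-fold) lower. SSX2, HABP4, ANKRD46 and CARNMT1 passed the test over both lines (edgeR adjusted p between 0.0170 and 0.0468). RGS19, OGFR, NOLC1 and DKK1 did not. WWTR1, DKK1, IGSF3, FAM234B and CARNMT1 have CTATGAA or TCTATGA in their 3' UTRs, and ANKRD46 does not. The pseudogenes MTX1P1 (3.70-fold higher) and MEMO1P1 (3.86-fold lower) can share reads with their parent genes and are uncertain, as is SSX2, which has near-identical paralogs. Simulated unchanged libraries gave 207 genes at 2-fold in this line, again without an expression minimum within the line. At an FPKM of at least 5, 49 genes were higher and 83 lower of 7278.

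The lines were then compared in their response. Across 10988 genes expressed in both, the log2 ratios correlated with Pearson r = 0.440 and Spearman rho = 0.431; these are correlations across genes, which are not independent replicates, and the pairs of libraries shared no control. The same sign was seen for 64.7% of these genes. Genes at least 2-fold lower in both lines numbered 37, against 1.06 for independent lists, and included SLC7A11, ANKRD1, PDIA6, SDHD, WWTR1 and both lincRNAs. Genes at least 2-fold higher in both numbered 7, against 0.451, among them TPM4 and SSX2. At an FPKM minimum of 5 these counts were 24 lower and 2 higher, and with a prior count of 0.5 they were 40 and 15. In 8 genes the shifts were at least 2-fold in opposite directions. Without the genes whose 3' UTR holds CTATGAA or TCTATGA, a choice made after the data were seen, 16 genes were at least 2-fold lower and 7 at least 2-fold higher in both lines.

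**Figure D4:**
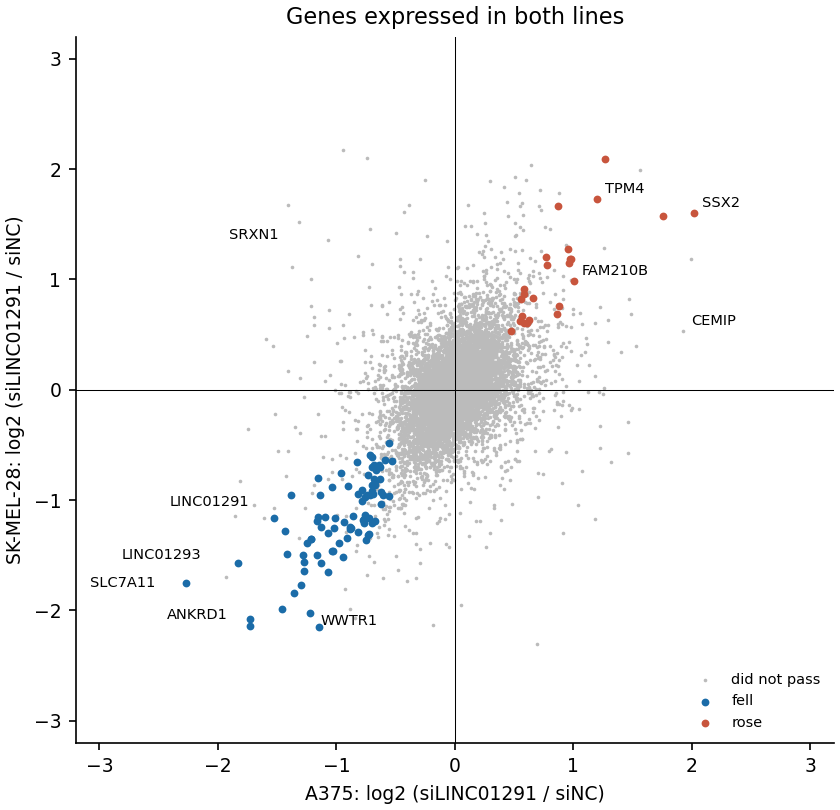
Log2 ratio of siLINC01291 to siNC in A375 (x axis) against SK-MEL-28 (y axis) for 10988 genes expressed in both lines. Blue genes fell and red genes rose over both lines, and 1 gene lies outside the axes; SLC7A11, LINC01293, ANKRD1 and WWTR1 lie at the lower left, and SRXN1 lies at -1.31 and 1.52.

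Gene groups were compared as lists fixed before the data were examined. Within a line, a list stood apart when its median log2 ratio lay outside the central 95% of 10000 random lists of the same size and expression, a description of these libraries only. Over both lines, limma's camera with its preset correlation of 0.01 called 10 lists (Benjamini-Hochberg adjusted p under 0.05). None of the 10 held with an estimated correlation, which rests on the fit's 1 residual degree of freedom. Hardly any list could pass there, and lists with and without a call at the preset correlation got the same adjusted p = 0.771 (limma's camera). This alternative therefore cannot tell strong lists from weak ones. The preset treats members as nearly independent, so its p-values may be too small for lists whose members move together.

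The median of pigment cell genes was higher and that of genes of the dedifferentiated melanoma state lower in both lines. The melanocyte differentiation list had a median log2 ratio of 0.32 in A375 (14 expressed members, random lists -0.14 to 0.13) and 0.17 in SK-MEL-28 (24 members, -0.11 to 0.06). The camera call was upward (limma's camera, adjusted p = 0.00394, and adjusted p = 0.771 with an estimated correlation). Of 24 members tested singly, 0 passed over all genes, and 6 rose and 1 fell when adjusted over the list alone. The largest ratios belonged to the melanosome chloride channel OCA2 (0.62 over both lines), TRPM1 (0.57) and CDK2 (0.44), none of which passed over all genes; OCA2 and TRPM1 are hardly expressed in A375 (FPKM 0.109 and 0.0304 in siNC), so their values rest on SK-MEL-28. Not all members were higher: PAX3 stood at -0.43 and MC1R at -0.22 over both lines (named after their values were seen), and MITF at -0.10 in A375. The melanosome matrix protein PMEL, chosen after its values were seen, stood at 0.33 in A375 and 0.34 in SK-MEL-28. The dedifferentiated list had medians of -0.24 in A375 (23 members, random -0.13 to 0.05) and -0.38 in SK-MEL-28 (15 members, -0.14 to 0.13), with a downward call by limma's camera (adjusted p = 5.09e-08, and adjusted p = 0.771 with an estimated correlation). Only ANKRD1 of its 23 tested members fell over all genes, and 8 fell when adjusted over the list alone. The matrix cross-linker LOXL2 (-0.67) and SLIT2 (-0.50) did not pass.

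Mitotic genes were lower mainly in SK-MEL-28. The mitosis list had a median of -0.55 there (28 members, random lists -0.11 to 0.06) and of -0.13 in A375 (28 members, -0.11 to 0.03). In SK-MEL-28, cyclin A2 (CCNA2) was 1.87-fold lower, the kinase AURKA 1.81-fold, the kinesin KIF20A 1.78-fold and PLK1 1.63-fold lower, and 27 of the 28 members lay below the median of the line's expressed genes. The call by limma's camera was downward (adjusted p = 1.58e-07, and adjusted p = 0.771 with an estimated correlation), but 0 of 28 members passed singly, and 0 when adjusted over the list alone. No member of this list has CTATGAA or TCTATGA in its searched 3' UTR (0 of 28). The DNA replication list was lower in A375 (median -0.19, 30 members, random -0.10 to 0.05) and not apart in SK-MEL-28 (-0.08), with a downward call by limma's camera (adjusted p = 0.00612, and adjusted p = 0.771 with an estimated correlation); GINS1 alone fell of 30 members, over all genes and over the list alone. CDT1 (-0.37), CCNE1 (-0.33) and RFC3 (-0.32) did not pass. Whether the lines differ in either list was not tested.

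Stress response genes were lower in A375 and were mixed in SK-MEL-28. Heat shock and oxidative stress genes were lower in both lines (medians -0.18 and -0.22, 25 members each; limma's camera downward, adjusted p = 5.58e-05, and adjusted p = 0.771 with an estimated correlation). Thioredoxin reductase TXNRD1 fell over all genes (-0.65, SE 0.07, edgeR adjusted p = 0.0218), and 9 of 25 members fell when adjusted over the list alone; the heat shock genes HSPA1A (-0.59) and HSPA1B (-0.64), near-identical copies and so uncertain singly, did not pass over all genes. Genes of the unfolded protein and integrated stress response had a median of -0.27 in A375 and 0.14 in SK-MEL-28 (24 members each, random -0.11 to 0.05 and -0.11 to 0.07). SLC7A11 was its only faller of 24, over all genes and over the list alone; CHAC1 stood at -1.53 and 0.40, and CEBPB at -0.95 and -0.16. Its camera call was downward (adjusted p = 0.0306), as were those of the ferroptosis list (adjusted p = 0.0261; medians -0.08 and -0.11, not apart in either line) and of the glycolysis and hypoxia list (adjusted p = 0.00612; -0.11, and -0.17 apart in SK-MEL-28); each has an adjusted p = 0.771 with an estimated correlation (limma). Without the genes that hold CTATGAA or TCTATGA, which include SLC7A11, the calls on the unfolded protein response and ferroptosis ended (adjusted p = 0.603 and 0.158, limma's camera), as they did at an FPKM minimum of 5 (0.192 and 0.126). In these, SLC7A11 was the only faller of 22 and the glucose transporter SLC2A1 (-0.84, SE 0.08) of 28, both also over the list alone, and SLC2A1 has a CTATGAA or TCTATGA word in its 3' UTR.

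Adhesion, matrix and signalling genes pointed in different directions. The epithelial-mesenchymal transition list was higher in A375 (median 0.13, 20 members) and lower in SK-MEL-28 (-0.22, 17 members); fibronectin (FN1) fell in both (-0.61, SE 0.06, edgeR adjusted p = 0.0161), the only passing member of 21, against 1 risen and 1 fallen when adjusted over the list alone. FN1 also holds a CTATGAA or TCTATGA word. Collagens and matrix genes were higher in A375 (0.24, 18 members, random -0.13 to 0.05) and not apart in SK-MEL-28 (0.07); 0 of 19 passed, and 2 rose and 1 fell over the list alone. Limma's camera did not call the list (upward, adjusted p = 0.114), but did at an FPKM minimum of 5 (0.0499) and without the genes that hold CTATGAA or TCTATGA (0.0183), with an adjusted p = 0.771 with an estimated correlation on the full list. MAPK output genes were lower in SK-MEL-28 (-0.19, 23 members) and level in A375 (0.00); 0 of 25 passed, and 1 rose and 4 fell over the list alone, with HMGA2 at -0.64 and PLAUR at -0.51, which both hold either word. IGF and PI3K-AKT signalling genes were higher in A375 (0.11, 26 members) and not apart in SK-MEL-28 (-0.02), and 0 of 25 passed either way. Immediate early genes were higher in SK-MEL-28 (0.21, 19 members) and not apart in A375 (-0.06). JUN fell (-0.65, SE 0.09, edgeR adjusted p = 0.0468), the only passing member of 19, against 6 risen and 1 fallen over the list alone.

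Inflammatory, immune and death-related lists gave few passing members. CXCL8, which codes for interleukin 8, fell (-1.35, SE 0.13, edgeR adjusted p = 0.0171), the only faller of 18 in the NF-kB and cytokine list, where 2 fell over the list alone; its medians were -0.15 in A375, where it stood apart, and -0.03, with a downward camera call (adjusted p = 0.0378, adjusted p = 0.771 with an estimated correlation, and 0.0812 at an FPKM minimum of 5). Interferon response genes were higher in A375 (0.15, 16 members) and not apart in SK-MEL-28 (-0.03); 0 of 19 passed, and 1 rose and 1 fell over the list alone. Antigen presentation genes were not apart (-0.02 and -0.05), and 0 of 21 passed either way. Among p53 targets, the death receptor FAS (-1.17, SE 0.17) and ZMAT3 (-0.80, SE 0.11) fell of 23, and 3 fell over the list alone; the median was 0.07 in A375 and -0.12 in SK-MEL-28, where it stood apart. Apoptosis regulators had medians of -0.10 and -0.12, apart in SK-MEL-28; 0 of 22 passed, and 1 rose and 4 fell over the list alone. FAS was hardly expressed in SK-MEL-28 (FPKM 0.274 in siNC and 0.122 in siLINC01291). FAS and ZMAT3 carry CTATGAA or TCTATGA. Without the genes that carry these words, the p53, apoptosis and MAPK lists no longer stood apart in SK-MEL-28 (-0.02, -0.03 and -0.09).

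Metabolic and housekeeping lists mostly stayed near the other genes. Transcripts encoded in the mitochondrial genome were lower in A375 (-0.27, 13 members, random -0.17 to 0.02) and not apart in SK-MEL-28 (-0.06); their share of counts was 3.28% and 2.87% in the A375 siNC and siLINC01291 libraries and 6.35% and 6.38% in those of SK-MEL-28. The camera call was downward (adjusted p = 0.0306, adjusted p = 0.771 with an estimated correlation, and 0.0812 at an FPKM minimum of 5), and 0 of 13 passed either way. Nuclear genes of oxidative phosphorylation were not apart (-0.02 in each line), although SDHD (-1.58) and NDUFS3 (-0.65, SE 0.10) fell of 27; over the list alone 1 rose and 2 fell. Ribosomal protein genes were not apart (-0.02 and 0.01), while RPL5 fell (-1.24, SE 0.12, edgeR adjusted p = 0.0148), the only faller of 35 both ways; RPL5 has processed pseudogenes that can share its reads. Argonaute AGO2 fell (-1.05, SE 0.15, edgeR adjusted p = 0.0468) of 13 RNA interference genes, both ways, with medians of 0.00 and -0.09. SDHD, NDUFS3, RPL5 and AGO2 all carry CTATGAA or TCTATGA. Cholesterol synthesis genes were slightly lower in A375 (-0.10) and not apart in SK-MEL-28 (-0.02); 0 of 24 passed, and 1 rose and 1 fell over the list alone. Replication-dependent histones were higher in A375 (0.47, 7 members) and not apart in SK-MEL-28 (0.03, 5 members). Of 6 tested, 0 passed, and 1 rose over the list alone. The list was chosen as histones whose transcripts end without poly(A), and the libraries were enriched with oligo(dT) beads. These values may therefore not reflect the level of histone transcripts. Markers of other cell types were sparse: 2 fibroblast, 5 keratinocyte, 2 immune and 3 endothelial markers were expressed in A375 and 1, 1, 1 and 0 in SK-MEL-28. The keratinocyte list was not apart in A375 (-0.05); 0 passed in any of these lists, and 1 keratinocyte marker fell over the list alone. Median and test differed in sign over both lines for the epithelial-mesenchymal transition (median just above 0), p53 (0.03), antigen presentation (0.01), ribosomal protein (just above 0) and keratinocyte (0.02) lists, whose direction in limma's camera was downward (adjusted p = 0.379, 0.316, 0.974, 0.316 and 0.268). Median and mean differed in sign for p53 targets (mean -0.08), immediate early genes (0.07) and MAPK output (0.02) in A375 and for collagens (-0.08), ribosomal proteins (-0.04) and cholesterol synthesis (0.01) in SK-MEL-28.

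**Figure D5:**
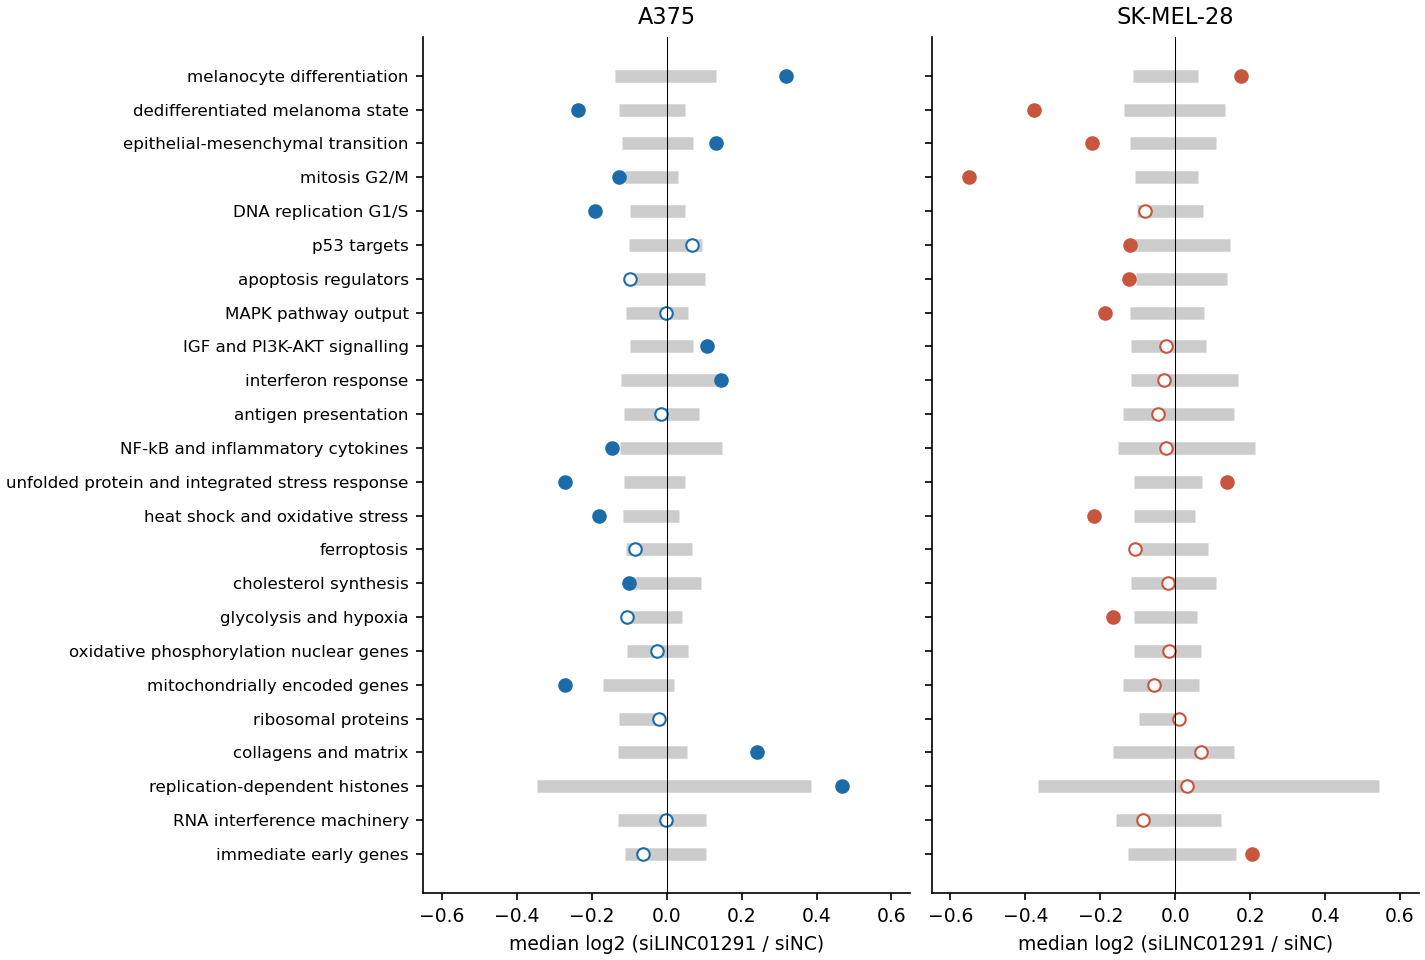
Median log2 ratio of siLINC01291 to siNC of each gene list with at least 5 expressed members in both lines, in A375 (left) and SK-MEL-28 (right). Grey bars span the central 95% of random lists of the same size and expression; filled points lie outside it, as the mitosis list does at -0.55 in SK-MEL-28.

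The baseline of the lines was compared with the treatment as a covariate, as background to the pigment cell lists. SK-MEL-28 expressed pigment cell genes far above A375: 23 of 24 members of the melanocyte list were higher and 1 lower. MITF, the master regulator of melanocytes, had an FPKM of 60.6 in SK-MEL-28 siNC and 5.68 in A375 siNC, and PMEL of 804 and 1.64. Genes of the dedifferentiated state showed the opposite, with 20 of 23 lower in SK-MEL-28, among them the receptor tyrosine kinase AXL (FPKM 0.667 against 125). In all, 4877 genes were higher and 4895 lower in SK-MEL-28 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13501 genes, 2 libraries per line). LINC01291 was among the higher genes (log2 0.67, SE 0.13, edgeR adjusted p = 0.00395). This estimate includes the siLINC01291 libraries, where 34.5% (A375) and 44.5% (SK-MEL-28) of the siNC level was left. In the siNC libraries alone its normalised CPM was 25.5 in A375 and 36.7 in SK-MEL-28. The 2 libraries of a line differ in treatment and are not replicates.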

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

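The tests of the control siRNA and of the genes next to LINC01293 were chosen only after the results were seen; the other tests of this part were written down before theirs.

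Results that pointed in opposite directions in the 2 lines drew attention. The epithelial-mesenchymal transition list had a median log2 ratio of 0.13 in A375 and -0.22 in SK-MEL-28. The list of the unfolded protein and integrated stress response had -0.27 in A375 and 0.14 in SK-MEL-28. SRXN1, a sulfiredoxin that repairs oxidised peroxiredoxins, had -1.31 in A375 and 1.52 in SK-MEL-28. None of these differences between the lines was tested, since each group holds 1 library.

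The genes that changed in both lines may in large part be targets of the siRNAs themselves through short seed matches. CTATGAA, the 3' UTR word with the lowest log2 ratios, reached t = -24.9 against -4.90 for the lowest of 100 shuffles, ranked first in each line and lies within the word TCTATGAA of the annotated LINC01291 transcripts, as the seed of an siRNA against LINC01291 would, although 21.2% of the tested words occur in those transcripts; TCGGAGA, the word with the highest ratios (t = 9.87), could in the same way mark targets of the control siRNA, lowered in the siNC libraries. Gene length and GC content as the whole cause are argued against: the median of the fallen genes moved from -1.02 to -0.98 (SE 0.04) and that of the risen genes from 0.89 to 0.85 (SE 0.10) after a fit on both was taken off. The siRNA sequences are not given in the sources used here, so a seed match stays a hypothesis. The biological explanation also stays open: loss of LINC01291 might free a microRNA that binds the same word. LINC01291, however, made up 0.136% (A375) and 0.181% (SK-MEL-28) of the summed FPKM of the 439 genes with TCTATGAA in the siNC libraries. The 14 fallen genes without either word in the searched 3' UTR could follow from loss of LINC01291 or indirectly from other siRNA targets. Neither was tested.

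LINC01293 fell together with LINC01291, which it follows at 1839 bases on the same strand. Reads that align to both annotated transcripts are argued against, since these share 0 words of 31 bases; reads of a longer transcript counted under LINC01293 are not covered by this. Lower transcription of the whole neighbourhood is likewise argued against, since the lowest log2 ratio of HK2 and POLE4 was -0.32 (HK2 in A375, interval -0.38 to -0.26), far from -1.83 for LINC01293. A candidate explanation that stays open is that both are parts of a single transcript, since the RefSeq gene table lists LINC01293 as a synonym of LINC01291; regulation of LINC01293 by LINC01291 also stays open, and neither was tested.

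Mitotic genes lower in SK-MEL-28 might reflect slower division after loss of LINC01291, which was not tested. Gene length and GC content are argued against, since the list's median was -0.45 (SE 0.06) after correction and -0.55 before. The shift was spread over the list, with 96.4% of the 28 members below the line's median. This largely restates a low median and is no independent evidence, since genes are not independent replicates. The estimated correlation of 0.857 rests on 1 residual degree of freedom. There it only records that most members differed between the lines in the same direction. Direct seed matches of the siRNA against LINC01291 in the searched 3' UTRs are argued against because 0 of the 28 members hold either word. Coding sequences and other 3' ends were not searched. Leaving out members with either word removes none, so the median of -0.55 without them adds nothing. A difference in cell density or handling between 2 single libraries could give the same values and stays open, as does an indirect result of other siRNA targets.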

How the results depend on the processing

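The alternative that leaves out genes with CTATGAA or TCTATGA in their 3' UTR was chosen after the data were seen; all other tests of this part were planned. In this part counts are given as higher then lower, or rose then fell. Of the values for single genes and lists, 1415 were counted as unchanged, 57 passed a threshold only under an alternative, 181 no longer passed and 45 moved (all on log2(FPKM + 1)). For genes within a line, unchanged meant a value inside the main counting interval, and for the others the same side of the threshold. Reversals numbered 0. Within a line that label was open only to genes changed at least 2-fold and to lists that stood apart. The cause was not tested unless stated.

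Within a line, counts of genes at least 2-fold changed followed the threshold and the expression minimum by construction. Each set gives A375 first, then SK-MEL-28 siLINC01291 against siNC, genes higher, then SK-MEL-28 siLINC01291 against siNC, genes lower. With no expression minimum they were 308 and 267 in A375 and 563 and 498 in SK-MEL-28; with an FPKM minimum of 5 they were 11 and 45, and 49 and 83. At 1.5-fold they were 523 and 522, and 780 and 627, and at 3-fold 19 and 20, and 45 and 34. On log2(FPKM + 1), where the added 1 shrinks ratios of low genes, they were 41 and 52, and 79 and 87. By list means, 7 lists stood apart in SK-MEL-28 in place of 11.

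For both lines together, siLINC01291 against siNC, genes that rose and fell (30 and 91) depended on the block: without the cell line term, which leaves the difference between the lines in the error, the counts were 0 and 0 (edgeR, 51 at an unadjusted p under 0.05). DESeq2 called 99 and 203, limma on log2(FPKM + 1) 1 and 5, limma with 0.1 added 0 and 0 (2120 at an unadjusted p under 0.05), and limma after quantile normalisation 0 and 0 (1999). An FPKM minimum of 5, which tests fewer genes, gave 5 and 27, no minimum 146 and 238, and a further 2-fold threshold 14 and 47. Without the genes that hold CTATGAA or TCTATGA, 109 rose and 65 fell. Of the 91 that fell before, 72 hold either word and were left out, and 19 were called again. With an estimated correlation, camera called 0 gene lists over both lines in place of 10. With 1 residual degree of freedom hardly any list could pass, so this cannot tell whether the calls depend on the correlation.

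The agreement between the lines, Pearson r (0.440), was 0.583 with an FPKM minimum of 5, 0.392 with a prior count of 0.5, 0.487 among genes at least 1.5-fold changed in a line and 0.365 without the genes that hold either word. For SK-MEL-28 against A375, genes higher numbered 3003 and for SK-MEL-28 against A375, genes lower 2997 with an FPKM minimum of 5, which tests fewer genes. Without the treatment term they numbered 4344 and 4257, against 4877 and 4895 with it. Depth limits calls on genes near the floor of 3 counts. Without an expression minimum within the line, 100 (A375) and 207 (SK-MEL-28) simulated unchanged genes passed 2-fold.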

Other observations

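The search for words and the tables without word-bearing genes, used in this part, are tests chosen only after the data were seen.

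Not every fallen gene held CTATGAA or TCTATGA in the 3' UTR searched. Words elsewhere in the transcripts were not searched. The 14 searched fallen genes without either word included ANKRD1 (-1.89), CXCL8 (-1.35), TXNRD1 (-0.65), JUN (-0.65) and ANKRD46 (-1.68) and, named after their values were seen, the keratin-associated protein gene KRTAP2-3 (-1.95, uncertain because near-identical copies exist), IGFN1 (-1.31), the carboxypeptidase CPA4 (-0.98) and the cell death suppressor TMBIM6 (-0.51). Among the risen genes searched, 2 of 28 held either word, STX12 (1.09) being 1 of them. When genes with either word were left out, 14 lists stood apart in A375 and 8 in SK-MEL-28, and limma's camera called 9 lists with the preset correlation, with collagens (upward) gained and the unfolded protein response and ferroptosis lost; an estimated correlation was not run on these reduced lists.

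Fibroblast and immune markers were low. The fibroblast marker LUM, a matrix proteoglycan, had FPKM of 3.25 and 3.74 in A375 and 7.84 and 8.07 in SK-MEL-28 (siNC and siLINC01291), and the immune marker LYZ, lysozyme, 1.57 and 1.94 in A375. Of 3 endothelial markers, KDR, a VEGF receptor, had FPKM of 0.784 and 2.37 in A375, and TIE1 of 2.01 and 1.84. The keratin gene KRT10 had 27.1 and 27.7 in A375 and 18.0 and 19.9 in SK-MEL-28.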
